A study of Sus scrofa with 22 samples.

How the data were processed

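Gene expression was measured in peripheral blood mononuclear cells of mini pigs with Affymetrix porcine arrays, 1 array per blood sample and 22 arrays in all. Per the labels' protocols, heparinised blood was separated on a Histopaque density gradient, RNA was purified with RNeasy Plus columns, and 4 µg of total RNA went into the One-Cycle biotin labelling. GCOS, RMA and Affymetrix Expression Console 1.1 were used, per the submitters' processing notes. The deposited values are RMA intensities on a linear scale, 1 value per probe set and array. The log2 of each intensity was taken here after a floor of 1. All 22 columns of values were used, and no raw scans were analysed here.

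The table held 24123 probe sets, of which 124 were Affymetrix control probe sets and were set aside. Gene symbols came from the annotation that accompanies the array, checked by Entrez ID against a pig gene table of assembly Sscrofa11.1, which was used for names alone. Of the remaining 23999 probe sets, 10069 carried 1 symbol and stood for 6765 genes, 198 carried several symbols, and 13732 had none. The gene table lacked 110 of the Entrez IDs and changed 0 symbols. A probe set was tested if its log2 value was above 5 in at least 2 arrays. This left 17240 probe sets (71.8%), 8426 of them with 1 symbol, for 5906 genes.

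Groups were taken from the labels. At time 0 there were 5 females and 5 males, and at 9 months 2 females and 2 males on each of 3 diets. The control chow held 5% beef tallow, the high-fat chow 20%, and the last group received the high-fat chow with resveratrol at 8 mg per kg body weight per day. The 22 arrays came from 20 pigs, since pigs 8 and 25 were measured at both times. To check whether the numbers mark the same animals, each pair's profiles, centred on their groups, were correlated across probe sets. The values were -0.056 for pig 8 and 0.199 for pig 25, against highest values of 0.348 and 0.198 with another time 0 pig of the same sex, so the profiles alone did not settle it, and the pairing rests on the labels.

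Comparisons were made with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for the block fits. Probe sets were tested two-sided with a moderated test and Benjamini-Hochberg adjustment over all those tested, at a threshold of 0.05. The comparisons of diets and of times used a fit of all 22 arrays with condition and an additive term for sex. The comparisons of the sexes and of the sex difference in a diet effect used 8 group means. Log2 differences are given with the standard error from that fit. The number of arrays limits the precision, above all where each group of condition and sex has 2 arrays.

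Gene lists (24) were fixed by symbol, and the 23 with at least 3 measured genes were tested, 1 probe set per gene, the brightest over all arrays. They covered inflammatory cytokines, interferon-stimulated genes, lipid handling, cholesterol synthesis, cholesterol efflux, antioxidant genes, sirtuins and AMPK, oxidative phosphorylation, adhesion, Toll-like and scavenger receptors, antigen presentation, glucocorticoid-responsive genes, immediate early genes, ribosomal proteins, the cell cycle, X-linked and Y-linked genes, and markers of T, B, NK, monocytic, granulocytic, platelet and erythroid cells. The Y-linked list was too short to test. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The preset calls did not hold with an estimated correlation in any comparison (0 lists called in each). With limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 12 lists passed for time, 9 for the sexes at 9 months and 0 in each other comparison.

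Named genes followed a rule. In each comparison these were the 10 largest positive and 10 largest negative changes past the threshold, filled to 5 by the smallest p where a direction had fewer than 10, and the 3 members with the smallest p of each list called or holding a passing member. In the sex comparisons the passing X-linked and Y-linked genes were added. Interaction contrasts took the 5 smallest p. A pair of genes that the rule names for time is not reported here. Unnamed probe sets appear by ID, with each point written as _, where they were among the 2 largest changes in a direction. The groups, comparisons, tests, filter, lists, naming rule and a first set of alternatives were chosen before the data were examined.

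The control probe sets differed between arrays in a way that the labels do not explain. The poly-A spike-in controls, which are added to the RNA before labelling, were used to cut the arrays into 4 sets (A to D). The cut was made at the largest gap within each time. Set C alone was cut further in the same way by the hybridization control BioB, to 5 sets. The number of sets follows from this rule, and that they are labelling batches is an inference. Alternatives built on these sets, and on the log2 difference between 3' and 5' actin probe sets as a measure of RNA integrity, were added after seeing the data. The other alternatives were the filter, cyclic loess normalization, variance and weight settings, the arrays included, the sex term, pig number as a block, the threshold, and each array left out in turn. The closing section states where they changed a count or a call.

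The fits were tested on simulated data drawn for the 17240 probe sets, with 100 probe sets changed per size. At a log2 change of 1, 94% were recovered for the sexes at time 0, 91% for high-fat against control diet, 100% for time and 52% for the sex difference of the high-fat effect. At a log2 change of 2 the recovery was 100%, 100%, 100% and 94%. In the high-fat comparison a simulated shift of 0.5 in the oxidative phosphorylation list was called, with 0 of the other lists. These values hold for the simulated data and do not give the power or list specificity in the real arrays. In the real high-fat comparison CPT1A, at 1.19 (SE 0.21), did not pass. When the arrays of that comparison were split in other ways, a median of 5 lists was called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.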

Results

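Expression was measured on 22 arrays of blood mononuclear cells from mini pigs, a fraction that holds lymphocytes and monocytes. There were 10 arrays at time 0 and 12 at 9 months, 4 per diet, with the sexes balanced within each diet. Arrays of the same group correlated closely across probe sets (26 pairs, median r 0.986, lowest 0.973), and arrays of different groups had a median r of 0.969 over 205 pairs. The first principal component held 35.1% of the variance and parted the times, and the second held 15.7%. The balance of monocyte and T cell markers differed between conditions. The mean of the monocyte list minus that of the T cell list was -0.72 ± 0.35 (SD, n = 10) at time 0, 0.15 ± 0.15 (SD, n = 4) on the control diet at 9 months, -0.45 ± 0.36 (SD, n = 4) on the high-fat diet and -0.22 ± 0.70 (SD, n = 4) with resveratrol. The mean log2 value of the poly-A spike-in controls was 9.13 in labelling set A (2 time 0 females), 7.69 in set B (the other 8 time 0 arrays), 8.76 in set C (7 arrays of 9 months) and 10.2 in set D (5 arrays of 9 months). The sets were cut within each time, so none could hold arrays of both. Across the times, sets A (9.12 to 9.15) and C (8.39 to 9.02) lay close together. The 3' minus 5' actin difference was 1.42 ± 0.50 (SD, n = 10) at time 0, and 1.95 ± 0.65, 2.36 ± 0.56 and 1.86 ± 0.67 (SD, n = 4 each) on the control, high-fat and resveratrol diets.

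**Figure D1:**
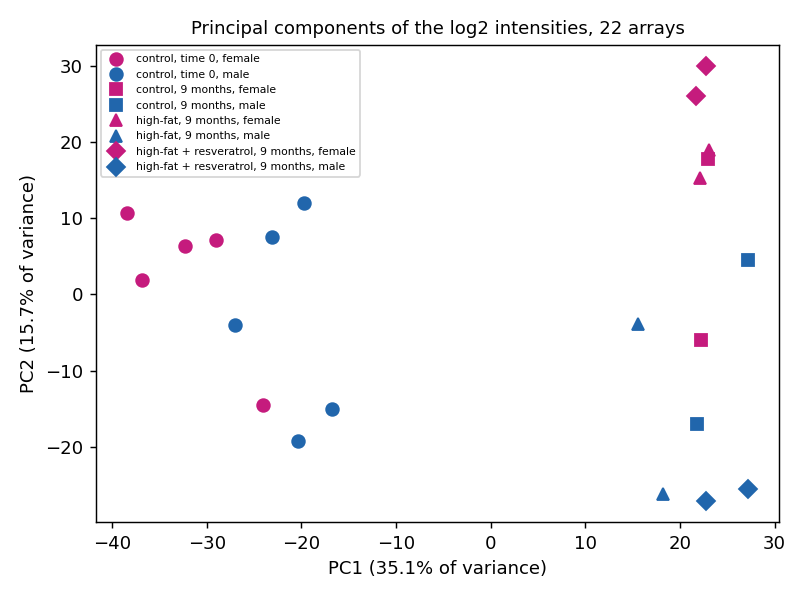
Principal components of the 22 arrays from the tested log2 values, 1 point per array, with shapes for diet and time, colours for sex and the share of variance on each axis. The first component (35.1%) separates time 0 from 9 months.

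Sex at the start of the experiment. Female mononuclear cells had less CPT1A, the enzyme that gates fatty acid entry into mitochondria (probe set Ssc_8974_1_S1_at). Its log2 value was 8.58 ± 0.16 (SD, n = 5) in females and 9.74 ± 0.16 (SD, n = 5) in males, a difference of -1.16 (SE 0.10, adjusted p = 1.71e-06), and it passed in each of the alternatives run. Females were also lower for NR4A2 (-0.79) and NR4A3 (-1.20), nuclear receptors induced within minutes of stimulation, for the regulators CREM (-0.86), TGIF1 (-0.84) and KLF11 (-0.82), and for SERPINB2 (-1.44), an inhibitor of plasminogen activators. They were higher for FN1 (1.02), which encodes fibronectin, for the complement inhibitor SERPING1 (0.67), the hexokinase HK3 (0.77), GIMAP5 (0.64), a GTPase of lymphocyte survival, and for FAM26F (1.05), B3GNT3 (0.91), STAMBPL1 (0.83), ARV1 (0.65) and TMEM106A (0.64). Y-linked EIF1AY gave the largest difference of a named gene, -6.79 (SE 0.11, adjusted p = 1.72e-18). X-linked TXLNG was 0.87, EIF1AX 0.50 and USP9X 0.45, and the probe set annotated as ZFX was -1.50. LOC396706 (-2.29) and the unnamed Ssc_13426_1_A1_at (5.86), Ssc_6667_1_A1_at (5.41), Ssc_16426_1_S1_at (-8.65) and Ssc_7473_1_A1_at (-8.15) also passed.

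All 20 measured interferon-stimulated genes, the antiviral programme, had positive female minus male differences (median 0.58, camera adjusted p = 9.84e-08; adjusted p = 0.750 with an estimated correlation). None of them passed over all genes (0 of 20), and 14 were higher when adjusted over the list alone. DDX58 differed by 0.92 (adjusted p = 0.0810) and MX1 by 0.99 (adjusted p = 0.0972), without passing. The list mean of male 24 was 9.12, above the other males' highest of 8.24. Oxidative phosphorylation genes were positive for 51 of 57 members (median 0.11, camera adjusted p = 7.89e-05; adjusted p = 0.750 with an estimated correlation), with NDUFB10 higher (0.32) and 3 higher when adjusted over the list alone. Immediate early genes had a median of -0.15 (camera adjusted p = 0.0117; adjusted p = 0.750 with an estimated correlation). NR4A2 and NR4A3 were the 2 lower over all genes, and 5 were lower and 1 higher when adjusted over the list alone. Single members of other lists passed: the proteasome subunit PSMB10 (0.49), the T cell cytokine receptor IL7R (-0.42) and the monocyte gene AIF1 (0.53). Named members that did not pass were STAT2 (0.49), the lipid genes HADH (0.34) and PLIN2 (-0.47), NDUFA9 (0.29) and ATP5J (0.35) of the respiratory chain, TAP1 (0.37), PSME2 (0.29), DNAJB1 (-0.31), CTLA4 (-0.71, adjusted p = 0.0501), CD3D (-0.31), FCGR1A (1.13, adjusted p = 0.0501) and CD14 (-0.51). Median, mean and test did not share a sign for cholesterol efflux, glucocorticoid-responsive, cell cycle and B cell genes, none of them called.

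In total 85 probe sets were higher and 99 lower in females (184 of 17240; 2832 at unadjusted p under 0.05). Labelling set A held both females 6 and 10, and without them 28 probe sets passed, 27 of them among the 184. Of the 30 named genes with a call, 10 then kept it, among them CPT1A (-1.22), EIF1AY, TXLNG, ZFX, LOC396706 and FAM26F (0.81, adjusted p = 0.0489), while FAM26F lost its call with the set as a block (adjusted p = 0.243). The interferon list kept its call without set A (median 0.50, camera adjusted p = 2.12e-07), and oxidative phosphorylation (0.03, adjusted p = 0.124) and immediate early genes (-0.08, adjusted p = 0.245) did not. Leaving out 1 array moved the count to 110 without female 8, 49 without female 10, 368 without female 17, 395 without female 20, 38 without male 11, 43 without male 12 and 54 without male 25, and ended the immediate early call without female 6 (adjusted p = 0.106) or female 8 (adjusted p = 0.0686).

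High-fat against control diet. With an additive sex term no gene passed over both sexes for 9 months of the high-fat chow, and CPT1A was the named gene with the smallest p. It was 9.31 ± 0.28 (SD, n = 4) on the high-fat diet and 8.12 ± 0.15 (SD, n = 4) on the control diet, a difference of 1.19 (SE 0.21, adjusted p = 0.0996), with each high-fat array above each control array. Within the sexes CPT1A passed, at 1.05 in females (adjusted p = 0.0370) and 1.32 in males (adjusted p = 0.00339), among 4 probe sets called in females and 5 in males. Both control females of 9 months lay in labelling set C and both high-fat females in set D, so diet and set cannot be told apart in females. SLC25A20, the carnitine carrier that works next to CPT1A, differed by 0.66 (SE 0.15, adjusted p = 0.218). Further positive values were those of SKA2 (0.60), a spindle protein, DR1 (0.51) and CLP1 (0.50). Negative values were those of the lysosomal peptidase TPP1 (-0.69, SE 0.13, adjusted p = 0.179), RENBP (-0.63), CCDC93 (-0.45), the receptor chaperone LRPAP1 (-0.52) and the protease inhibitor A2M (-1.06). Within the lipid list, adjusted over the list alone, CPT1A, SLC25A20 and FABP4 were higher and the lipase PNPLA2 lower, while over all genes 0 passed. The FABP4 value came from the 2 high-fat females alone. The median of that list was -0.01, its mean 0.06 and its test pointed up (camera adjusted p = 0.763). The X-linked and granulocyte lists, not called, also differed in sign between median and test.

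Monocyte and dendritic cell markers were negative in all 14 measured members (median -0.52, camera adjusted p = 1.42e-07; adjusted p = 0.334 with an estimated correlation), and 7 were lower when adjusted over the list alone. SPI1, the master regulator of myeloid cells, differed by -0.68, CTSD by -0.53 and CST3 by -0.27, none past the threshold over all genes. Cell cycle genes were positive in 20 of 21 members (median 0.37, camera adjusted p = 1.28e-09; adjusted p = 0.412 with an estimated correlation), with 3 higher when adjusted over the list alone. BIRC5 differed by 0.68, STMN1 by 0.51 and CKS2 by 0.40, each with an adjusted p of 0.326. These 2 lists kept their calls with each array left out. Within labelling set C the medians were -0.36 and 0.55 and within set D -0.40 and 0.40, but set C holds 1 high-fat array and set D 1 control array, so these values lend little weight.

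Smaller shifts were called for Toll-like and scavenger receptors (median -0.25, camera adjusted p = 0.00559; adjusted p = 0.412 with an estimated correlation), with CD14 at -0.76, CD163 at -0.90 and TLR8 at -0.83, and for cholesterol efflux genes (median -0.21, camera adjusted p = 0.0295; adjusted p = 0.412 with an estimated correlation), with NR1H3 at -0.58, ABCA1 at -0.63 and LPCAT3 at -0.26. T cell markers (median 0.13, camera adjusted p = 0.0403; adjusted p = 0.707 with an estimated correlation) included CD3G at 0.29, LEF1 at 0.24 and LCK at 0.21. Oxidative phosphorylation (median 0.03, camera adjusted p = 0.0414; adjusted p = 0.764 with an estimated correlation) included COX7C at 0.29, ATP5B at 0.17 and SDHA at -0.21. In each of these 4 lists 0 members passed, over all genes or adjusted over the list alone. Each lost its call when 1 array was left out. Without control female 8 the adjusted p was 0.130 for the receptors, 0.0998 for efflux, 0.226 for T cells and 0.130 for oxidative phosphorylation. Without control male 16 it was 0.186 for efflux and 0.0783 for oxidative phosphorylation, without control male 25 it was 0.0509 for T cells and 0.0654 for oxidative phosphorylation, and without high-fat female 27 it was 0.0620 for efflux and 0.0730 for T cells. Without high-fat female 30 it was 0.0673 for the receptors and 0.186 for T cells, and for oxidative phosphorylation it was 0.517 without high-fat male 23 and 0.125 without high-fat male 26.

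With limma 0 of 17240 probe sets passed for the high-fat diet (smallest adjusted p 0.0996), and 1562 had an unadjusted p under 0.05, 670 higher and 892 lower. The zero depended on the fit. The additive term takes 1 sex difference for all conditions. For CPT1A the sex difference at time 0 less that at 9 months over all diets was -0.97 (adjusted p = 0.00254). The SE of its high-fat difference was 0.21 with the additive term and 0.11 with 8 group means. With 8 group means 18 passed, CPT1A (adjusted p = 4.80e-05) among them, and with array weights 68 passed, among them CPT1A (adjusted p = 0.0121), TPP1 (adjusted p = 0.0121), CCDC93 (adjusted p = 0.0145) and SLC25A20 (adjusted p = 0.0300). Over all alternatives the adjusted p of CPT1A lay between 4.80e-05 and 0.595 and that of SLC25A20 between 0.0300 and 0.919, the highest within set D. Without control female 8 there were 18 calls, with CPT1A at 1.23 (adjusted p = 0.0439), and without high-fat female 27 there was 1.

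**Figure D2:**
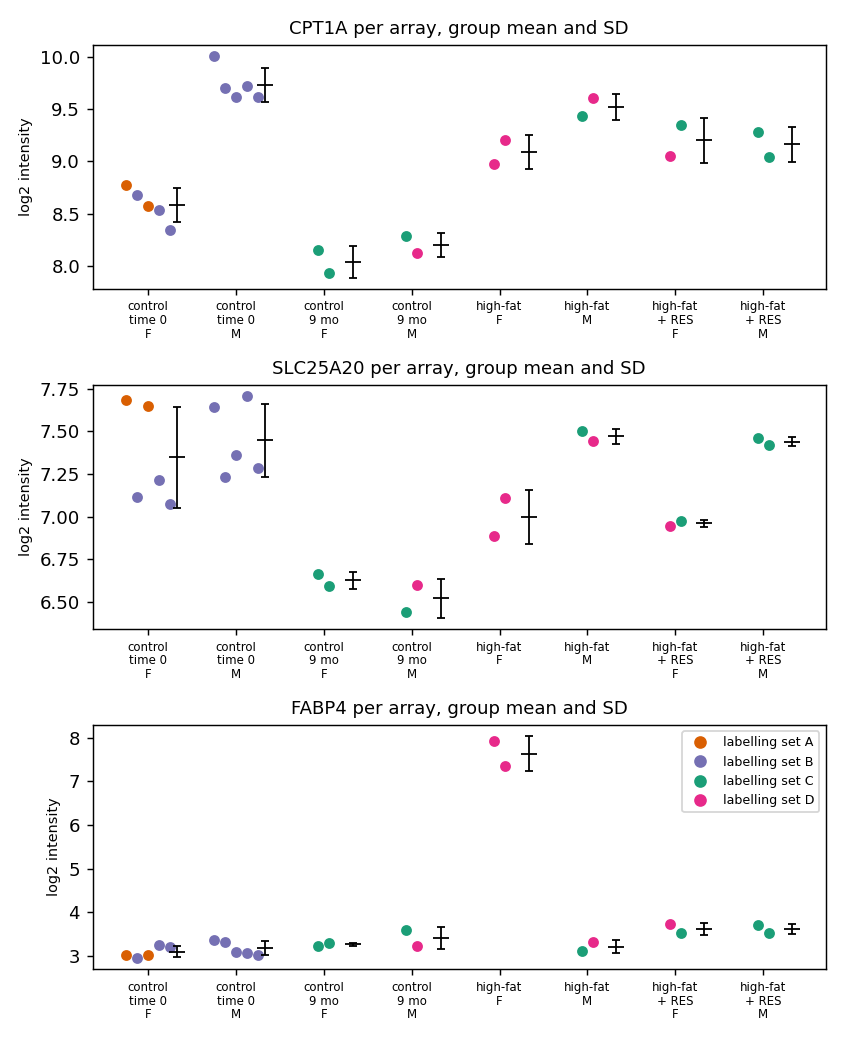
Log2 intensity of CPT1A, SLC25A20 and FABP4 per array in the 8 groups of condition and sex, with colours for the labelling set and bars for group mean and SD. CPT1A is higher in each array of both high-fat groups than in each control array of 9 months, and FABP4 stands out in the 2 females on the high-fat diet.

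Resveratrol added to the high-fat diet. This comparison asks what resveratrol did in animals on the same fat intake. No gene passed, and the named genes with the smallest p had an adjusted p of 0.728 each. They were GPM6B (0.52), CLN3 (0.63), the deacetylase HDAC6 (0.51), WDFY3 (0.38) and the glutathione synthase GSS (0.28) on the positive side. On the negative side they were SKA2 (-0.55), CYP3A22 (-0.40), the chromatin protein HMGB1 (-0.41), the globin HBB (-0.57) and the cohesin subunit RAD21 (-0.53). The cell cycle list was negative in 20 of 21 members (median -0.21, camera adjusted p = 1.74e-06; adjusted p = 0.923 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. STMN1 differed by -0.37, TOP2A by -0.53 and CCNB1 by -0.43. Within labelling set D, which holds 1 resveratrol array, the median of that list was 0.12. The sirtuin and AMPK list had a median of 0.06 (camera adjusted p = 0.757) and the antioxidant list one of -0.00394 with a mean of 0.03 (camera adjusted p = 0.975). Signs of median, mean and test also differed for inflammatory, cholesterol synthesis, oxidative phosphorylation, B cell and granulocyte genes, none of them called. With limma 0 probe sets passed and 1143 had an unadjusted p under 0.05.

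Across the 17240 probe sets the resveratrol differences ran against the high-fat differences (r = -0.608), but both share the high-fat arrays and probe sets are not independent replicates. Independent noise with no effect gave r of -0.498 (-0.547 to -0.462), and 100 sex-balanced regroupings of the same arrays gave a median of -0.520, with 27 as low as the observed value. With the high-fat arrays divided between the contrasts, so that the contrasts shared no array, r was -0.155 (-0.300 to -0.142 over 4 divisions). Of the 1562 probe sets with an unadjusted p under 0.05 for the high-fat diet, 1497 (95.8%) had the opposite sign under resveratrol, a count that carries the same dependence on shared arrays.

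High-fat diet with resveratrol against control diet. CPT1A (1.06, SE 0.21) and SLC25A20 (0.63, SE 0.15) were again the named lipid genes with the smallest p, with an adjusted p of 1.00. CPT1A was 9.05 or higher in the 4 resveratrol arrays against at most 8.28 in the controls, and with 8 group means it passed alone (adjusted p = 0.000514). Other values were those of the actin ACTA2 (1.18), the adhesion protein ICAM2 (0.52), TM4SF1 (0.52), FGD1 (-0.48), CHI3L1 (-1.22), OAF (-0.58), VLDLR (-0.40) and NR2F6 (-0.31). With limma 0 probe sets passed and 664 had an unadjusted p under 0.05.

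Monocyte markers were the list that kept its call with each array left out (11 of 14 negative, median -0.37, camera adjusted p = 0.000154; adjusted p = 0.383 with an estimated correlation), with CD163 at -0.86, SPI1 at -0.45 and CTSD at -0.39. The list means were 8.97 and 9.16 in resveratrol females against 9.72 and 9.54 in control females, and 9.70 and 9.78 against 9.93 and 9.62 in males, a contrast of the sexes that was not tested. Further positive shifts were called for NK and cytotoxic markers (0.32; GZMH 0.40, GNLY 0.56, KLRK1 0.43), platelet markers (0.62; SELP 1.07, PPBP 1.59, ITGB3 1.22), interferon-stimulated genes (0.23; ISG15 0.53, ISG20 0.63, ISG12(A) 0.43), oxidative phosphorylation (0.05; COX7A2 0.23, NDUFB7 0.17, NDUFA11 0.21) and the cell cycle (0.10; CKS2 0.26, BIRC5 0.45, CCNA2 0.22). Negative shifts were called for cholesterol synthesis (-0.17; ACAT2 -0.23, SQLE -0.29, SREBF2 -0.18), cholesterol efflux (-0.19; NR1H3 -0.36, LPCAT3 -0.21, APOE -0.33) and Toll-like and scavenger receptors (-0.12; TLR8 -0.51, TLR4 -0.37). The camera adjusted p was 0.00846 for NK, platelet, oxidative phosphorylation, efflux and receptor lists, 0.0162 for interferon, 0.0164 for cholesterol synthesis and 0.0240 for the cell cycle. None held with an estimated correlation (adjusted p = 0.383 at the lowest), and 0 members passed in these 9 lists. The uncalled lipid, antioxidant, ribosomal and erythroid lists differed in sign between median, mean and test.

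Leaving out 1 array ended the call of each of these lists except monocyte markers. Without control female 8, whose platelet mean was far below the other controls, the adjusted p was 0.698 for platelets, 0.590 for interferon, 0.378 for cholesterol synthesis, 0.283 for receptors and 0.158 for NK markers, and 4 lists were left. Without resveratrol male 4, also with 4 lists left, it was 0.190 for platelets, 0.293 for interferon, 0.121 for cholesterol synthesis, 0.294 for NK markers and 0.0764 for oxidative phosphorylation. Without resveratrol male 5 the interferon median was 0.04 with a test that pointed down (adjusted p = 0.885), and oxidative phosphorylation had 0.101. Without control male 16 interferon had 0.196 and efflux 0.201. The cell cycle had 0.278 without control female 18, 0.352 without control male 25, 0.629 without resveratrol female 21 and 0.285 without resveratrol female 22. Resveratrol female 21 also decided efflux (0.0523), and resveratrol female 22 cholesterol synthesis (0.0992) and the receptors (0.0934).

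**Figure D3:**
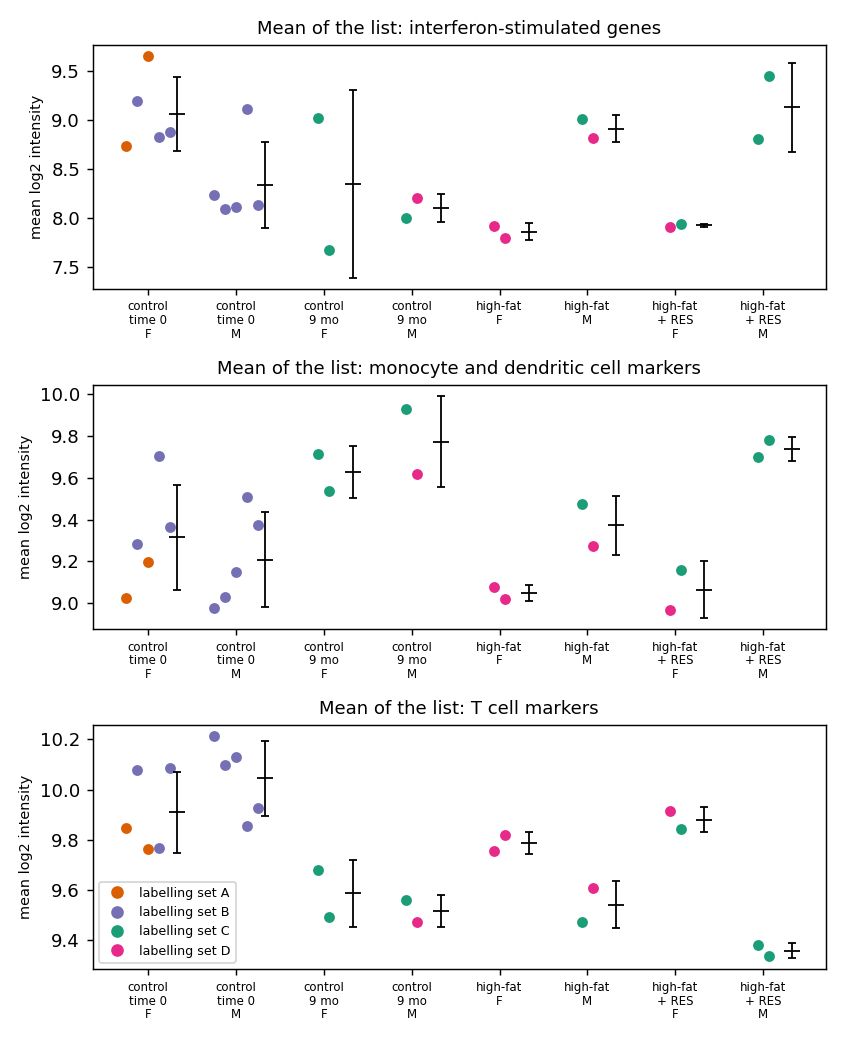
Mean log2 intensity of interferon, monocyte and T cell lists per array in the 8 groups of condition and sex, with colours for the labelling set and bars for group mean and SD. Monocyte markers lie lower in the high-fat arrays and the resveratrol females than in the controls of 9 months, and interferon-stimulated genes lie lower in females than in males on both high-fat diets.

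Control animals at 9 months against time 0. This was the widest difference in the series, and it went with a different balance of cell markers. The labelling sets were cut within each time, so they differ between the times by definition. CTR9, a subunit of a complex that accompanies RNA polymerase, rose (2.34, SE 0.17, adjusted p = 1.31e-08), as did the helicase DDX46 (2.18), PPIG (1.85), the RNA-binding HNRNPU (1.84), the amino acid transporter SLC38A1 (2.06), the collagen receptor subunit ITGA2 (2.12) and STBD1 (1.81). CTR9 went from 6.85 ± 0.25 (SD, n = 10) to 9.18 ± 0.16 (SD, n = 4). The red cell genes AHSP (-1.90), HBM (-1.63) and RHCE (-1.35) fell, with the arginase ARG1 (-1.46), the complement regulator CD55 (-1.65), MAT2B (-1.38), the splicing factor SF1 (-1.35) and KLK7 (-1.34). LOC100154873 (-2.65) and LOC100627879 (-1.58) also fell. The largest unnamed changes were Ssc_27280_1_A1_at (3.21), Ssc_22970_1_S1_at (3.13) and Ssc_14247_2_A1_at (-2.08).

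Oxidative phosphorylation fell in 35 of 57 members over all genes and in 37 when adjusted over the list alone (median -0.31, camera adjusted p = 5.21e-07; adjusted p = 0.398 with an estimated correlation), with NDUFC1 at -0.77, NDUFA13 at -0.52 and SDHC at -0.52. Immediate early genes rose in 14 of 21 members (median 0.60, camera adjusted p = 2.43e-06; adjusted p = 0.398 with an estimated correlation), with NR4A3 at 2.03, FOSL2 at 1.36, GADD45B at 1.34 and IER5 at 0.60. The cell cycle fell in 13 of 21 members and rose in 1 (median -0.59, camera adjusted p = 0.00208; adjusted p = 0.507 with an estimated correlation), with CCNB1 at -1.05, CDC20 at -0.90 and RRM1 at -0.65. T cell markers fell in 8 of 16 (median -0.42, camera adjusted p = 0.00208; adjusted p = 0.398 with an estimated correlation), with CD3G at -0.88, CD8A at -0.85 and LEF1 at -0.53. Monocyte markers rose in 5 of 14 (median 0.38, camera adjusted p = 0.00513; adjusted p = 0.398 with an estimated correlation), with CD163 at 1.07, LGALS3 at 0.90 and IRF8 at 0.77, and Toll-like and scavenger receptors in 6 of 14 (median 0.30, camera adjusted p = 0.0109; adjusted p = 0.398 with an estimated correlation), with TLR8 at 1.05 and TLR1 at 0.64. Adjusted over the list alone, the counts were 14 higher for immediate early genes, 14 lower and 1 higher for the cell cycle, 8 lower for T cells, 5 higher for monocytes and 7 higher for the receptors.

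The other lists were not called by camera but held members that changed. Limma's fry passed the 6 lists above and 6 of these: lipid genes (adjusted p = 4.26e-05), sirtuins and AMPK (0.000885), cholesterol efflux (0.00541), B cell (0.00541), erythroid (0.00676) and adhesion genes (0.0281). Lipid genes fell in 13 and rose in 3 of 36 (camera adjusted p = 0.0519), with SLC25A20 at -0.82, ACADM at -0.58 and ACSL5 at -0.49, and cholesterol efflux genes rose in 3 of 13 (camera adjusted p = 0.0519), with ABCA1 at 1.30, APOE at 0.60 and LIPA at 0.46. In the cholesterol synthesis list (2 rose and 4 fell of 12) INSIG1 was 0.96, HSD17B7 -0.58 and FDPS -0.40. Interferon-stimulated genes fell in 4 of 20 (median -0.54, camera adjusted p = 0.131), with GBP1 at -1.07, GBP2 at -0.74 and IRF9 at -0.58. Erythroid genes fell in 6 and rose in 1 of 10 (camera adjusted p = 0.149; adjusted p = 0.507 with an estimated correlation), with HBB at -0.81 and SELENBP1 at 0.52. B cell genes fell in 3 of 4, with CD79B at -0.70, SPIB at -0.50 and JCHAIN at -0.50. In the NK list 3 fell and 1 rose of 8, with GNLY at -0.84, GZMH at -0.55 and FASLG at 0.54. Of the inflammatory list 4 rose and 1 fell of 22, with IER3 at 1.41, TNFRSF1B at 1.00 and NFKBIA at 0.50. Antioxidant genes rose in 3 and fell in 8 of 28, with TXNRD1 at 1.17, PRDX5 at -0.56 and TXN2 at -0.34. In the sirtuin and AMPK list 6 rose and 4 fell of 17, with NAMPT at 0.87, PRKAB1 at 0.66 and TFAM at 0.58. Adhesion genes rose in 4 and fell in 1 of 18, with CCR1 at 1.71, CD58 at 0.59 and ITGB1 at -0.33. Antigen presentation genes rose in 4 and fell in 9 of 25, with SLA-7 at 0.92, PSMB10 at -0.87 and SLA-6 at -0.62. Glucocorticoid-responsive genes rose in 4 and fell in 2 of 12, with PER1 at 0.73, NR3C1 at 0.60 and FKBP5 at -0.72. X-linked genes rose in 2 and fell in 1 of 7 (ZFX 0.80, TXLNG 0.36, EIF1AX -0.35). The granulocyte list had ARG1 lower, with CHI3L1 (0.69) and ELANE (-0.24) not passing, and the platelet list had SPARC higher (0.23), with PPBP (-0.90) and CLU (-0.99) not passing. No ribosomal protein gene of 57 passed with limma, and their median was -0.01 with a test that pointed up (camera adjusted p = 0.957).

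In total 2726 probe sets were higher and 3300 lower at 9 months (6026 of 17240, 35.0%; 7672 at unadjusted p under 0.05). With pig number as a fixed block, where the contrast rests on pigs 8 and 25, 110 passed, 105 of them among the 6026, and all 82 named genes with a call kept their direction. Those still past the threshold (15) included CTR9, SLC38A1, HNRNPU, AHSP, HBM and ARG1.

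**Figure D4:**
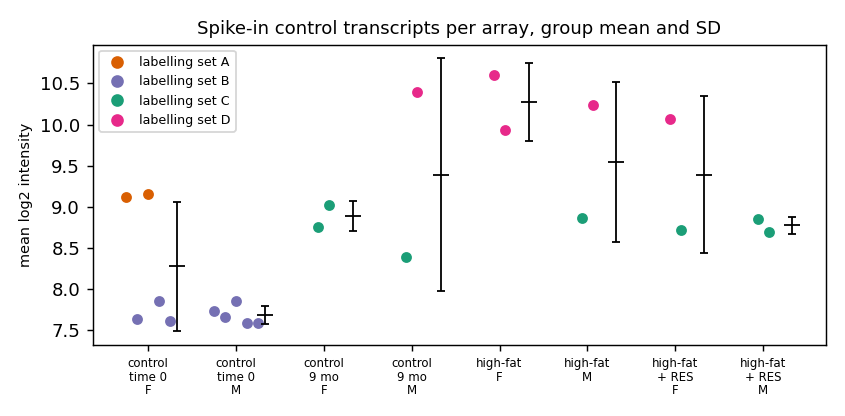
Mean log2 intensity of the poly-A spike-in controls per array in the 8 groups, with colours for the labelling set and bars for group mean and SD. The sets were cut within each time, so none could hold arrays of both, and set means run from 7.69 (B) to 10.2 (D).

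Sex differences in the response to diet. FABP4, a fatty acid binding protein of fat cells and macrophages (Ssc_1089_1_S1_at), was above the filter level of 5 in 2 arrays alone, those of the high-fat females, at 7.92 and 7.35, and was at most 3.72 in the other arrays of 9 months. The fitted high-fat difference in females was 4.37 (adjusted p = 5.13e-11) and the difference between the sexes 4.57 (adjusted p = 8.98e-09). With resveratrol the fitted values were -4.01 (adjusted p = 2.27e-10) in females and -4.42 (adjusted p = 1.59e-08) between the sexes, which rest on the same 2 high-fat females. Since all other arrays lay below the filter level, the sizes in females rest on values below it and are uncertain. The fitted values between the sexes also hold differences between male arrays that lay below it. The p-values take their spread mostly from arrays below that level, so they do not measure the spread among pigs that express FABP4. With only the arrays compared, limma's adjusted p between the sexes was 0.0130 for the high-fat diet and 0.00746 for resveratrol. FABP4 was the single call for the high-fat diet (2015 at unadjusted p under 0.05), and it passed in each alternative that tested it. The other named genes did not pass: MORC3 (-1.33), VPS26A (-1.03), METTL18 (-1.06) and ATG9B (0.61), each with an adjusted p of 0.397. For resveratrol 2 probe sets were called (1009 at unadjusted p under 0.05), FABP4 and the unnamed Ssc_29841_1_A1_s_at (-2.08, adjusted p = 0.0134). CYSLTR2 (-1.57), ASXL1 (0.67), CARMIL2 (0.87) and VEGFB (0.75) did not pass.

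The female minus male difference of the high-fat effect was negative for 18 of 20 interferon-stimulated genes (median -1.20, camera adjusted p = 4.55e-06; adjusted p = 0.850 with an estimated correlation), with OAS1 at -4.52, MX2 at -2.19 and IFI44L at -0.86, none of them past the threshold. The 2 control females had list means of 9.03 (female 18) and 7.67 (female 8), and the median was -0.65 (adjusted p = 0.0405) without female 18 and -1.76 without female 8. Oxidative phosphorylation (median -0.17; NDUFC1 -0.64, NDUFA5 -0.59, UQCRB -0.50) and platelet markers (median 1.38; CLU 3.32, ITGB3 2.32, ITGA2B 1.98) had a camera adjusted p of 0.00199 each (adjusted p = 0.850 with an estimated correlation). Without control female 8 the platelet median was 0.22 (adjusted p = 0.278), and with cyclic loess oxidative phosphorylation was -0.06 (adjusted p = 0.140). In these 3 lists 0 members passed, over all genes or adjusted over the list alone. In the lipid list FABP4 passed, while ACSL3 was -1.04 and ACSL4 -0.53 without passing. That list had a negative median (-0.06) and a positive mean (0.08) and test.

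For resveratrol, cell cycle genes were positive in 20 of 21 members (median 0.54, camera adjusted p = 8.19e-05; adjusted p = 0.572 with an estimated correlation), with UBE2C at 1.24, STMN1 at 0.72 and HMGB2 at 0.51. Negative sex differences were called for NK markers (-0.45, camera adjusted p = 0.00193; FASLG -0.75, KLRK1 -0.77, FCGR3A -0.32), monocyte markers (-0.34, camera adjusted p = 0.0116; VCAN -1.01, CD163 -1.12, AIF1 -0.48) and granulocyte markers (-0.51, camera adjusted p = 0.0116; S100A9 -1.07, CHI3L1 -1.09, S100A12 -0.61). Platelet markers (-0.47; PPBP -1.35, GP9 -0.34, SPARC -0.22), immediate early genes (-0.19; EGR1 -0.91, NR4A3 -0.90, HSP70.2 -0.61), adhesion genes (-0.11; ALOX5AP -0.94, ITGB1 -0.44, CCR2 the most negative) and glucocorticoid-responsive genes (-0.10; KLF9 -0.57, THBD -1.72) had a camera adjusted p of 0.0399 each. All had an adjusted p = 0.572 with an estimated correlation, and 0 members passed. FASN (0.84) and ACSL3 (0.98) of the lipid list did not pass. The inflammatory, lipid, efflux, sirtuin and antigen presentation lists, none of them called, differed in sign between median, mean and test.

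Leaving out 1 array moved these results. The high-fat count was 10 without control female 18, 4 without control female 8, 154 without control male 25 and 75 without high-fat male 26, and the resveratrol count was 54 without high-fat male 26. The unnamed Ssc_29841_1_A1_s_at lost its call without high-fat female 30 (adjusted p = 0.123), high-fat male 23 (0.0923), resveratrol female 22 (0.188), resveratrol male 4 (0.154) or resveratrol male 5 (0.0641), over a range of 0.00561 to 0.201 in all alternatives, and the count was then 1. Among the resveratrol lists the cell cycle kept its call throughout. The NK call ended without resveratrol male 4 (adjusted p = 0.0642), the monocyte call without high-fat male 26 (0.121) and the granulocyte call without high-fat female 27 (0.0936) or high-fat male 26 (0.280). Platelet markers lost theirs without high-fat female 30 (0.402), high-fat male 26 (0.122), resveratrol female 22 (0.209) or resveratrol male 4 (0.360), and immediate early genes without high-fat female 27 (0.214), high-fat male 23 (0.137), resveratrol female 22 (0.113) or resveratrol male 4 (0.130). Adhesion and glucocorticoid-responsive genes each lost theirs for 6 of the 8 arrays, with the highest adjusted p at 0.151 without high-fat male 26 for adhesion and at 0.123 without resveratrol female 21 for glucocorticoid-responsive genes.

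Sex at 9 months. This comparison takes the mean over the 3 diets. The proteoglycan VCAN of monocytes was lower in females (-1.31, SE 0.16, adjusted p = 0.000219), as were the calprotectin subunit S100A9 (-1.25), CASP1 (-1.30), the chemokine AMCF-II (-1.70) and THBS1 (-1.53), and the red cell genes AHSP (-2.19), HBM (-1.93) and ALAS2 (-1.66). CYP2C91 (-1.84), MRAS (-1.36) and LOC100154873 (-1.82) were also lower. The B cell receptor subunit CD79B (0.97), THY1 (0.90), the lipoxygenase ALOX15 (1.07), CHD7 (0.81), KIAA1191 (0.84), SLC15A2 (0.81), C4BPB (0.80), ACTG2 (1.11) and PHACTR3 (1.03) were higher. FABP4 was higher by 1.43, a mean set by the high-fat females. Of the genes on the X-linked and Y-linked lists EIF1AY (-6.34) and the probe set annotated as ZFX (-1.11) were lower. TXLNG (0.74), KDM6A (0.71), EIF1AX (0.43) and USP9X (0.31) were higher. LOC396706 (-2.22), on neither list, was also lower. Among unnamed probe sets Ssc_13426_1_A1_at (5.88) and Ssc_31029_1_A1_at (5.45) were higher and Ssc_16426_1_S1_at (-8.37) and Ssc_7473_1_A1_at (-7.95) lower.

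All 20 interferon-stimulated genes were negative (median -0.63, camera adjusted p = 6.94e-07; adjusted p = 0.325 with an estimated correlation). On the control diet the list means were 9.03 and 7.67 in females and 8.00 and 8.20 in males. XAF1 (-1.17) and MX1 (-1.04) were the 2 lower, 13 were lower when adjusted over the list alone, and OAS1 was -2.23 without passing. Granulocyte markers were negative in all 10 (median -0.55, camera adjusted p = 0.000109; adjusted p = 0.151 with an estimated correlation), with S100A9, CHI3L1 (-0.97) and S100A12 (-0.71) lower. Monocyte markers had 4 lower and 1 higher of 14 (median -0.46, camera adjusted p = 0.000342; adjusted p = 0.299 with an estimated correlation), with AIF1 at -0.61 and FCN1 at -0.75. Antioxidant genes had 7 lower of 28 (median -0.12, camera adjusted p = 0.000342; adjusted p = 0.151 with an estimated correlation), with MGST1 at -0.54, MSRA at -0.36 and GSR at -0.30. Erythroid markers had 3 lower of 10 (median -0.31, camera adjusted p = 0.00110; adjusted p = 0.151 with an estimated correlation). T cell markers were positive in 15 of 16 (median 0.24, camera adjusted p = 0.00110; adjusted p = 0.258 with an estimated correlation), with CD3E (0.54) and GATA3 (0.53) higher, and B cell markers had 2 higher of 4 (median 0.46, camera adjusted p = 0.0159; adjusted p = 0.258 with an estimated correlation), CD79B and CD40 (0.58). The X-linked list had 4 higher and 1 lower of 7 (median 0.31, camera adjusted p = 0.00714; adjusted p = 0.151 with an estimated correlation). Adjusted over the list alone the counts were 5 lower for granulocyte markers, 7 lower and 1 higher for monocyte markers, 11 lower for antioxidant genes, 4 lower for erythroid markers, 6 higher for T cells, 3 higher for B cells and 5 higher with 1 lower for the X-linked list.

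Cholesterol efflux genes had 3 lower of 13 (median -0.13, camera adjusted p = 0.0104; adjusted p = 0.151 with an estimated correlation), NPC2 (-0.47), LIPA (-0.48) and NR1H3 (-0.39). Toll-like and scavenger receptors had 3 lower of 14 (median -0.37, camera adjusted p = 0.0228; adjusted p = 0.415 with an estimated correlation), LY96 (-0.57), TLR2 (-0.65) and TLR8 (-0.81), and 7 lower with 2 higher when adjusted over the list alone. Platelet markers had a median of -0.54 (camera adjusted p = 0.0235; adjusted p = 0.483 with an estimated correlation) and 0 passing members, with RGS18 at -0.78, PPBP at -1.19 and SELP at -0.68. The efflux call ended without control male 16 (adjusted p = 0.0991). The receptor call ended without control female 18 (0.0745), control male 16 (0.0967), high-fat female 30 (0.0931) or resveratrol male 4 (0.0543). The platelet call ended without control female 8 (0.248), control male 16 (0.119), high-fat female 27 (0.0897), resveratrol female 22 (0.0548) or resveratrol male 4 (0.0930).

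Members of lists that camera did not call also differed. FASN (0.70) was higher and ACSL4 (-0.43) lower among lipid genes, SREBF2 (0.31) and SCAP (0.34), regulators of cholesterol synthesis, were higher, and CD74 (0.70) was higher and CD86 (-0.45) lower among antigen presentation genes. ATP5J (-0.47), NDUFA9 (-0.30) and SDHB (-0.23) of oxidative phosphorylation, CCR2 (-0.92), TYROBP (-0.70), FCGR3A (-0.26), ANXA1 (-0.62), TXNIP (-0.61) and MCL1 (-0.23) were lower, and ITGA5 (0.76) was higher. Named members without a call were SOD2 (-0.26), IL18 (-0.54), ACAT2 (0.23), S1PR1 (0.28, adjusted p = 0.0501), CIITA (0.33), CD163 (-0.52), DNAJB1 (0.25), ZFP36 (0.34), CD4 (0.61, adjusted p = 0.0538), SPIB (0.33) and GZMH (0.25). The medians of the inflammatory (0.000201), lipid (-0.05) and antigen presentation (-0.00251) lists did not share the sign of their mean (-0.07, 0.02 and 0.05).

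In total 530 probe sets were higher and 506 lower in females (1036 of 17240, 6.01%; 3755 at unadjusted p under 0.05). With 5 labelling sets as a block 142 passed, 134 of them among the 1036, and 28 of 66 named genes kept their call, VCAN, ALOX15 and THY1 among them, while AHSP, MX1 and CD79B lost theirs. The count was 412 without control female 8, 514 without control male 25, 464 without high-fat female 27, 599 without high-fat female 30, 319 without high-fat male 23, 426 without resveratrol female 21, 559 without resveratrol female 22, 485 without resveratrol male 4 and 662 without resveratrol male 5. Of the 85 probe sets higher in females at time 0, 13 were higher at 9 months (2.61 expected by chance, Fisher's exact p = 1.85e-06) and 19 were lower (2.49 expected, Fisher's exact p = 3.88e-12). Of the 99 lower at time 0, 12 were lower at 9 months (2.91 expected, Fisher's exact p = 3.26e-05) and 9 were higher (3.04 expected, Fisher's exact p = 0.00342). Fisher's test takes the probe sets and the comparisons as independent, which they are not. Both comparisons share the variances of the same fit, and pigs 8 and 25 are in both. Sex-linked probe sets such as that of EIF1AY also count in the same-direction overlap. The overlaps are therefore given as counts, and no conclusion is drawn from their p-values.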

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

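All tests of the patterns weighed here, those with the actin difference and the labelling sets among them, were chosen only after the result they test was seen. For labelling set D and FABP4, the labelling set and CPT1A, monocyte balance and SLC25A20, and the joint rise of oxidation genes, the test's own values had been seen as well.

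FABP4 was high in the 2 females on the high-fat diet alone, with a fitted sex difference of 4.57 for the high-fat effect and -4.42 for resveratrol, both fitted with male arrays below the filter level. Both females lie in labelling set D, but the highest log2 value of FABP4 in the other arrays of set D was 3.72, and with the actin difference as a covariate the sex difference was 4.35, which argues against labelling and RNA degradation. Fat cells carried over with the blood would raise other fat cell genes, and the median sex difference of 9 markers was 0.0556, though one of them, ADIPOQ, was below the filter level in all arrays. A response of lipid-sensing macrophage genes could raise FABP4 as well, and its 6 measured genes had a median sex difference of 0.0533 with 4 positive, which leaves that open. Whether more high-fat females would show FABP4 cannot be told from 2 animals.

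The change over time took in 6026 probe sets. The labelling sets were cut within each time, so they cannot show whether the times shared a batch. A labelling batch may account for any part of the change. With the set as a random block 5034 were called, but sets A and B alone differed by 713 calls at time 0, and batch stays open. With the actin difference as a covariate 6982 were called, which argues against RNA degradation. With the monocyte minus T cell score as a covariate 5044 were called, 3706 of them (61.5%) among the 6026, so that score did not take up the whole difference. It does not cover B cell, NK or erythroid markers, members of which also changed, so a wider shift of cell types stays open. Age, growth, housing and batch remain together in this comparison.

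CPT1A and SLC25A20 had higher values on the high-fat diet without passing over both sexes in the fit with an additive sex term. With 8 group means in limma CPT1A passed (adjusted p = 4.80e-05) and SLC25A20 did not (adjusted p = 0.0669). With the labelling set as a block CPT1A was 1.18 and with the actin covariate 1.26, so the actin difference did not lower the value. In males each of these diets had 1 array in set C and 1 in set D, and the difference was 1.32. This argues against the labelling set in males. In females diet and set cannot be told apart, so labelling stays open there. With the monocyte score as a covariate CPT1A was 0.79 (SE 0.21) and SLC25A20 0.71, so a smaller share of monocytes could carry part of the CPT1A value and did not lower that of SLC25A20. A joint rise of fatty acid oxidation would move the other 14 measured oxidation genes, whose median was -0.00421 with 6 positive. A response of these genes alone to fatty acids stays open. In control animals SLC25A20 was lower at 9 months than at time 0 (-0.82, SE 0.13). The CPT1A mean of the 9-month controls also lay below that of either sex at time 0. The high-fat group has no arrays at time 0. Whether these genes rose on the diet or fell less than in controls cannot be told.

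Several other values stood apart. The unnamed Ssc_29841_1_A1_s_at had a sex difference of -2.08 for resveratrol. The lists called for the sex difference of the high-fat effect were interferon-stimulated genes (-1.20), oxidative phosphorylation (-0.17) and platelet markers (1.38). For resveratrol they were adhesion (-0.11), glucocorticoid-responsive (-0.10), immediate early (-0.19), cell cycle (0.54), NK (-0.45), monocyte (-0.34), granulocyte (-0.51) and platelet (-0.47) lists. None of the lists of either effect was called with an estimated correlation. The sex difference at time 0 less that at 9 months over all diets passed for 1265 probe sets and was 1.19 for interferon-stimulated genes, while control animals alone gave 0 probe sets and 0 lists. The poly-A spike-in controls averaged 10.2 in set D and 7.69 in set B.

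Of 145 Dixon tests of an extreme array within its group, 9 exceeded the critical value, where chance alone would give about 1 in 20. At time 0, male 24 had the highest interferon list mean (9.12), male 15 the lowest cholesterol synthesis mean (8.23), female 10 the highest antioxidant mean (10.2), male 25 the lowest B cell mean (9.46) and male 11 the highest CPT1A (10.0). At 9 months, high-fat male 23 had the lowest sirtuin list mean (8.26), control female 8 the lowest platelet mean (6.50, the next 8.49), control male 16 the highest FABP4 of its group (3.59) and resveratrol female 21 the highest spike-in mean (10.1). All arrays were kept.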

How the results depend on the processing

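The alternatives built on labelling sets, on set C or D alone, without set A and with the actin covariate were chosen only after the results were seen. Where a value below changed, the cause was not tested unless stated.

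For the sexes at time 0 the 184 calls became 43 with only the arrays compared, 25 with the labelling set as a block, 28 with 5 sets and 28 without set A. Leaving out 1 array gave 38 (male 11) to 395 (female 20). The lists called were 0 with an estimated correlation, 5 without set A (1 shared with the 3) and 3 to 6 with 1 array left out: 6 without female 10, 6 without male 24 and 5 without male 25.

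For the high-fat diet the count of 0 became 68 with array weights, 2 with only the arrays compared, 18 with 8 group means, 2 with the actin covariate, 157 within set C and 220 at unadjusted p under 0.05 with a fold of at least 1.5. Set C holds 1 high-fat array and set D 1 control array, so the spread of these was taken from the other groups. Leaving out 1 array gave 0 to 18. Called lists numbered 0 with an estimated correlation, 3 within set D and 2 (control female 8) to 9 with 1 array left out. Within set D the signs turned for ATP5B (-0.0174), CD3G (-0.00687) and LEF1 (-0.0048).

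For resveratrol against the high-fat diet the count of 0 became 1 with 8 group means, 154 within set C and 98 at the unadjusted threshold with a fold of at least 1.5. The number of lists was 0 with an estimated correlation, 2 with the mean of all probe sets of a gene, 3 with the set as a block, 5 with the actin covariate and 3 within set C. With 1 array left out they were 1 to 5: 5 without high-fat male 23, 3 without resveratrol female 21, and 2 each without high-fat female 30, resveratrol female 22 or resveratrol male 4. Within set D, with 1 resveratrol array, the signs turned for STMN1 (0.00597), TOP2A (0.0436) and the cell cycle list (0.12). The correlation with the high-fat differences was -0.592 for the brighter probe sets by mean, -0.607 with cyclic loess and -0.670 with the set as a block.

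For resveratrol against the control diet the count of 0 became 1 with 8 group means and 124 at the unadjusted threshold with a fold of at least 1.5. The lists called were 0 with an estimated correlation, 2 within set D and 4 to 8 with 1 array left out, the fewest without control female 8 or resveratrol male 4. Within set D, which sets resveratrol female 21 against control male 25, 1 array on each side, the signs turned for ISG20 (-0.0717), ACAT2 (0.0663), SREBF2 (0.14), KLRK1 (-0.25), the interferon list (-0.39) and the direction of the NK list's test (median 0.15). Within set C the cell cycle median was 0.0202 and its test pointed down. With 1 array left out the interferon median ran from 0.0401 to 0.522, and its test pointed down at the lowest, without resveratrol male 5.

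For time the 6026 calls became 110 with pig number as a fixed block and 2034 at the unadjusted threshold with a fold of at least 1.5, with 4867 to 6087 when 1 array was left out. As a random block, pig number added calls for CHI3L1 for time (0.72) and for S1PR1 in the sexes at 9 months (0.28), and no other call of a named gene changed. Called lists numbered 0 with an estimated correlation. Without control female 8 the platelet genes PPBP (0.11) and CLU (0.21) turned sign, while the other end of their ranges was -1.45 and -1.51. The labelling set could not be used as a fixed block here, since the sets were cut within each time, and was used as a random block. Values within a set could not be had for time or the interactions, and for the time 0 sexes the comparison without set A is the one within set B.

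For the sex difference of the high-fat effect the count of 1 became 0 in the brighter probe sets by mean, where FABP4 is filtered out, and 1075 at the unadjusted threshold with a fold of at least 1.5. It ran from 1 to 154 with 1 array left out. The number of lists was 0 with an estimated correlation, 5 with the actin covariate and 3 to 8 with 1 array left out: 8 without control male 16, 7 without high-fat male 26 and 5 without high-fat female 27.

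For that of the resveratrol effect the count of 2 became 0 in the brighter probe sets by mean, 1 with cyclic loess, 1 with only the arrays compared, 1 with the set as a block, 1 with 5 sets and 501 at the unadjusted threshold with a fold of at least 1.5. It ran from 1 to 54 with 1 array left out. Called lists numbered 0 with an estimated correlation, 3 with cyclic loess, 5 with the mean of all probe sets of a gene and 3 to 11 with 1 array left out: 3 without high-fat male 26, 4 without high-fat female 27 or resveratrol male 4 and 5 without resveratrol female 22. PPBP turned to 0.15 with 5 sets.

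For the sexes at 9 months the 1036 calls became 142 with 5 sets, 602 with the actin covariate, 33 within set C, 17 within set D and 437 at the unadjusted threshold with a fold of at least 1.5. Leaving out 1 array gave 319 to 1441. The lists called were 0 with an estimated correlation and 3 within set D, where SELP (0.0838) and the platelet list (0.10) turned sign. Cyclic loess moved the median log2 difference over all probe sets by less than 0.1 in each comparison.

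No count moved by more than 1.5 times without the filter, with trend and robust variances or without the sex term. In the brighter probe sets by mean 2 counts moved, those of the sex differences of the diet effects. Without the filter 8 named genes lost their call, NR4A3, NDUFB10 and IL7R at time 0 and ACTG2, SLC15A2, C4BPB, NR1H3 and MCL1 for the sexes at 9 months. With trend and robust variances CTLA4 at time 0 and S1PR1 at 9 months gained one and ACTG2 lost its call. Without the sex term ZFX, TXLNG and CD79B lost theirs for time.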

Other observations

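The tests of this part, those of sex by time and of the other splits, include the sex by time contrast, which was chosen only after the results were seen; the splits were planned.

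The sex difference at time 0, in control animals, was set against that at 9 months over all 3 diets, so time and diet are mixed. The female minus male difference at time 0 less that at 9 months was 1.48 for the complement inhibitor SERPING1, 2.23 for CASP1, 1.43 for VCAN, 1.13 for AIF1, 1.04 for GIMAP5, 1.02 for TNS3, 0.85 for MGST1, 0.81 for ATP5J and 0.77 for LYPLA1. It was -0.97 for CPT1A (adjusted p = 0.00254), -1.34 for KLF11 and -1.03 for DYNLL2. FABP4 also passed, through the 2 high-fat females alone. In total 1265 probe sets passed, 670 positive and 595 negative (3989 at unadjusted p under 0.05), and 597 with the labelling set as a block.

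For interferon-stimulated genes the contrast was positive (1.19, camera adjusted p = 7.06e-11; adjusted p = 0.369 with an estimated correlation), also with the set as a block (1.18, camera adjusted p = 1.53e-09). T cell markers (-0.35), antioxidant genes (0.12), monocyte (0.21), granulocyte (0.73) and erythroid markers (0.43) were called too, while oxidative phosphorylation (0.11) and immediate early genes (-0.19) lost their calls with the block (adjusted p = 0.126 and 0.286). Of the 8 lists called, 0 held with an estimated correlation. Control animals alone gave 0 calls with limma (1843 at unadjusted p under 0.05) and 0 lists, with the interferon list at 0.49 (adjusted p = 0.112), where 9 months has 2 arrays per sex, and the contrast was not tested between diets.

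The same arrays were also split in other ways, with as many arrays per side. For the sexes at time 0 the highest count of 100 splits other than the real one was 43 against 184. For time it was 1133 against 6026, so no other split drawn reached the real count in either comparison. Part of the lead at time 0 was fixed in advance, since the real split alone parts the sex-linked probe sets. Labelling set A held only females, so the splits cannot tell sex from labelling at time 0, nor time from batch. For the sexes at 9 months the highest was 2818 against 1036, and 3 of 100 splits were as large with the real one included. That share is under 0.05, but other groupings exceeded the real count, and the real split alone parts the sex-linked probe sets. The splits therefore do not settle whether chance could give this count. The highest split put control female 8 and control male 16 with the high-fat and resveratrol females, which points to structure of the samples besides sex. For the high-fat diet 6 of 35 splits had as many probe sets at unadjusted p under 0.05 as the real 1562 (highest 2610). For resveratrol 7 of 35 reached 1143, and the highest, 4797, was the split of females from males, again structure of the samples. For resveratrol against control 22 of 35 reached 664 (highest 3725). Chance cannot be excluded for these diet counts. The splits cannot settle it, since they were not held to equal numbers of each sex as the real diet groups were.

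Chance cannot be excluded for any count of called lists either, with the same limit of the splits for the diets. At least as many lists were called in 83 of 100 splits for the sexes at time 0 (real 3, highest 16), 13 of 35 for the high-fat diet (6, 9), 34 of 35 for resveratrol (1, 10), 3 of 35 for resveratrol against control (9, 11), 46 of 100 for time (6, 12) and 10 of 100 for the sexes at 9 months (11, 14).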
